A study of Mus musculus with 6 samples.

How the data were processed

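RNA was measured in CD8+ T cells recovered from subcutaneous B16-OVA tumours of C57BL6J mice. B16-OVA is a mouse melanoma line that expresses ovalbumin, a model antigen that CD8+ T cells can recognise. The series has 6 samples, 3 control and 3 Stub1 knockout (KO), all of the 2022 batch per the labels. Per the labels, total RNA was purified with a Qiagen RNeasy kit and made into libraries with the Takara SMARTseq v4 kit, which primes on poly(A) tails and does not mark strand. Stub1 KO 2 was set aside by the submitters per its label and is not analysed here, which leaves 3 control and 2 KO libraries, called Control 1, Control 2, Control 3, KO 1 and KO 3 after their titles. How Stub1 was removed, how the cells were isolated from the tumour, and whether each library came from a separate mouse are not given in the sources used here. If libraries shared a mouse or a pool of cells, the p-values measure only the spread between these samples, which may be technical.

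The submitters' processing notes name Salmon 1.8.0, R 4.4.1, DESeq2 1.44.0 and the GRCm39 build, with no further settings. The deposited estimated counts per gene symbol are whole numbers; Salmon assigns reads to transcripts by probability, and the rounding step is not given in the sources used here. Such counts can split reads between near-identical copies, so values of multigene families such as histones, serpins and class I MHC genes are uncertain. The deposited normalised signal equals the estimated counts divided by 1 factor per library, and these factors match median-of-ratios size factors of the same genes. That table holds the 11979 genes with more than 10 counts in every library, out of 32625 in the table of estimated counts. The authors' deposited comparison table gives, for the same 11979 genes, the mean signal, the log2 fold change with its standard error on the log2 scale, the Wald statistic as a score, the p-value and the adjusted p-value, which is NA for 465 genes. Its fold changes are knockout over control, since Stub1 is negative there. The reference annotation at hand is of an older build than GRCm39, so no coordinates are given; it served for gene symbols, for naming the mitochondrial genes and for the order of genes around Stub1 (GRCm38.p6).

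From the estimated counts, edgeR 4.0.16 in R 4.3.3 was run with TMM factors, its expression filter by group, and the quasi-likelihood F test without covariates. The filter kept 14490 genes. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and the standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM (counts over the library total, scaled to a common total) with TMM factors, computed here from the deposited estimated counts, and log2 values per library used a prior count of 2. The common biological coefficient of variation was 0.591 and the median of residual plus prior degrees of freedom was 6.13.

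A total of 39 gene lists was written before the data were examined, as were the tests, the groups and the rule for named genes; the settings added later are named below. The 39 lists cover T cell states and functions, IL-27 and interferon signalling, chaperones and proteasome, metabolism, cell cycle, RNA quality, and markers of other cells that a tumour sample could hold. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The erythroid list had no tested member, which left 38. Named genes are Stub1, Chic2 and Il27ra; the 10 largest rises and the 10 largest falls with adjusted p under 0.05, a mean of at least 5 CPM and every KO library beyond every control library, leaving out predicted genes and receptor segments; and up to 4 members per list with the smallest p. Single measures per library were compared with exact two-sided permutation tests over the 10 splits of the 5 libraries, whose smallest possible p is 0.1.

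The fit was tested on simulated counts for the same 14490 genes and library sizes, with 200 changed genes. It recovered 7% of the 2-fold changes and 67% of the 4-fold changes, with 0 calls of the wrong sign and 6 of 81 calls on unchanged genes. In that simulation a raised list of 30 genes was called and 0 of 30 unchanged lists were. Genes were drawn independently there, so this does not show how camera does when the genes of a list move together.

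Alternatives planned before the data were examined were other scaling factors, no filter or a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom with quality weights, a threshold of 0.1, a fold threshold of 1.5, the replicate number as a block, no receptor segments, and each library left out in turn. After the data had been seen, the submitters' filter, scaling to equal levels of the T cell receptor and co-stimulation list, a melanocyte covariate, and a fit with only Control 2 as control were added. Total counts ran from 41318384 to 90689080 per library, and 13529 to 14244 genes had 10 or more counts. Intervals for shares are exact Clopper-Pearson intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.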

Results

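The transcriptomes of CD8+ T cells from B16-OVA melanomas were compared between 3 control and 2 Stub1 KO libraries. Stub1 encodes a ubiquitin ligase that also acts as a co-chaperone, and the series title places it in a complex with CHIC2 that lowers the IL-27 receptor chain encoded by Il27ra. The comparison addresses what loss of Stub1 does to the RNA of T cells in the tumour. Total counts were 51404619 in Control 1, 49122747 in Control 2, 63003087 in Control 3, 41318384 in KO 1 and 90689080 in KO 3, so the knockouts are the shallowest and the deepest library.

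Stub1 mRNA was lower in both knockout libraries than in every control. Its level was 233, 181 and 204 CPM in the controls and 65.7 and 73.6 CPM in KO 1 and KO 3, a log2 fold change of -1.56 ± 0.178 (SE; edgeR quasi-likelihood, adjusted p = 0.0428). Chic2, the named partner, was at 66.7 ± 9.29 CPM (SD, n = 3) in controls and 70.8 ± 2.39 CPM (SD, n = 2) in knockouts, with a log2 fold change of 0.09 ± 0.191 (edgeR adjusted p = 0.829). Il27ra was at 45.1, 105 and 63.7 CPM in the controls and at 129 and 160 CPM in the knockouts, a log2 fold change of 1.02 ± 0.354 that did not pass the test (edgeR adjusted p = 0.159). DESeq2 on the same counts gave Il27ra an adjusted p of 0.0329 (range over all settings 0.0185 to 1), and the authors' deposited table gives 0.029. With libraries scaled to equal T cell gene levels the Il27ra value was 0.29 ± 0.343, and that of Stub1 was -2.47 ± 0.465. That scaling moved the median of all genes to -0.89, so both values include this common shift.

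**Figure D1:**
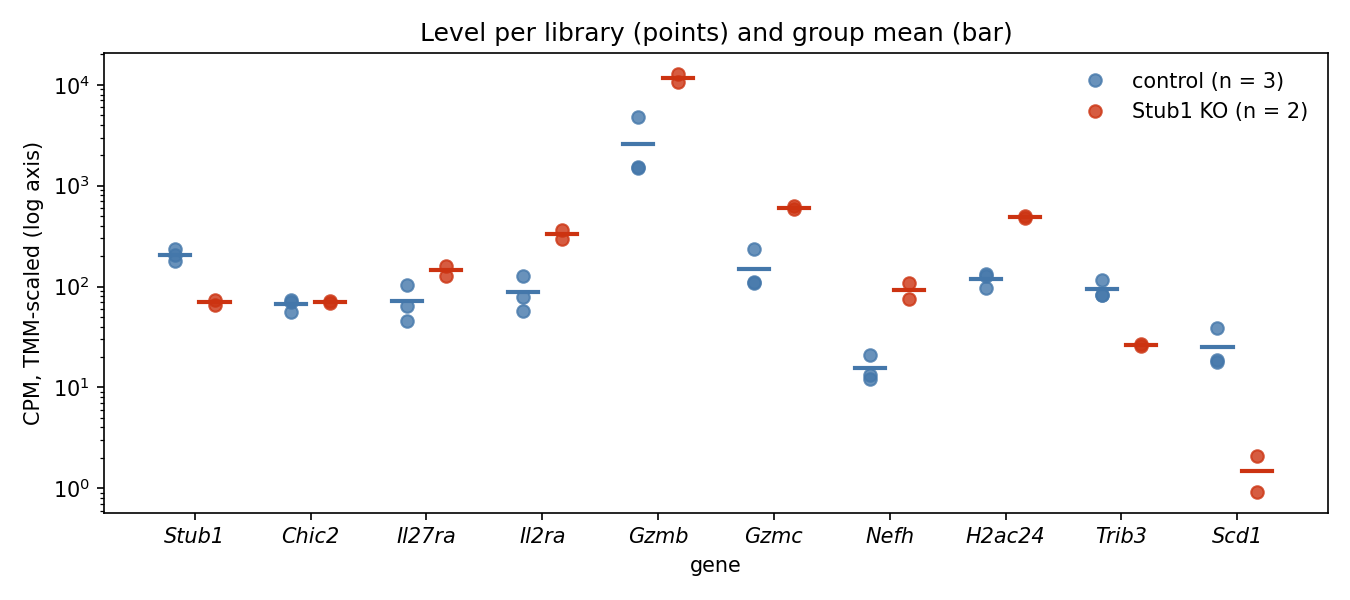
Levels of 10 named genes in CPM (log axis) for the 3 control libraries (blue) and the 2 Stub1 KO libraries (red); points are libraries and bars are group means. Stub1 lies at 181 to 233 CPM in controls and 65.7 to 73.6 CPM in knockouts, while Gzmb reaches 4797 CPM in Control 2 against 10666 and 12840 CPM in the knockouts.

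The knockout libraries held less melanocyte and macrophage RNA, more RNA of cell cycle genes relative to all genes, and a small set of sharply higher genes led by Msc, Nefh, Usp31 and H2ac24. The cell cycle lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.73 for G1/S and for G2/M) or with fry (adjusted p = 0.144 and 0.126). In edgeR, 269 of 14490 genes passed the threshold, 32 higher and 237 lower in the knockouts, with adjusted p between 0.0428 and 0.0498. The larger share of lower genes depended on the libraries and the tool: without Control 2 edgeR called 1191 higher and 1144 lower genes, and with all libraries limma-voom with quality weights called 1127 higher and 1493 lower. Melanocyte markers such as Dct took 1.86, 1.05 and 2.10% of counts in Control 1, Control 2 and Control 3, against 0.381% in KO 1 and 0.239% in KO 3. Macrophage markers took 0.534, 0.159 and 0.278% in the controls and 0.080 and 0.0786% in the knockouts. Genes of the T cell receptor and co-stimulation list took 0.504, 0.944 and 0.578% in the controls and 1.04 and 1.16% in the knockouts. As mean log2 levels, the melanocyte score was lower by -2.21 in knockouts (exact permutation p = 0.1, the smallest possible), the macrophage score by -1.51 (exact permutation p = 0.2), and the T cell score was higher by 0.81 (exact permutation p = 0.2).

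**Figure D2:**
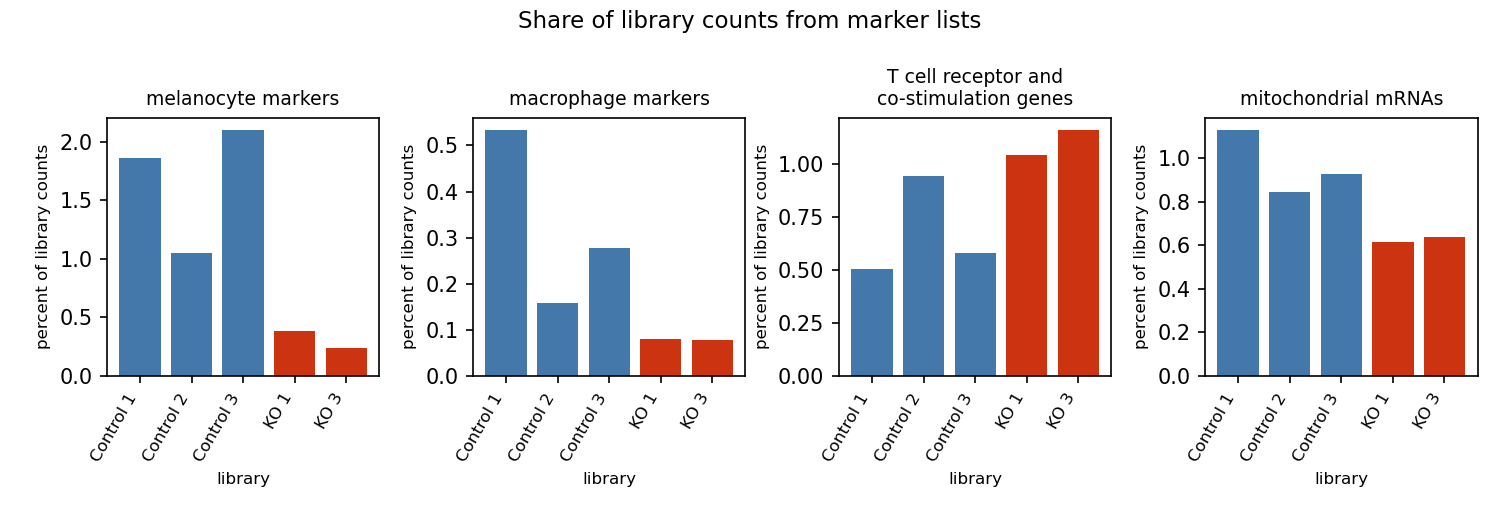
Percent of each library's counts from 4 gene lists, for the 3 controls (blue) and the 2 Stub1 KO libraries (red); bars are single libraries. Melanocyte markers take 1.05 to 2.10% in controls and 0.239 to 0.381% in knockouts, and Control 2 has the lowest melanocyte and the highest T cell share of the controls.

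Among the largest rises, Msc, a helix-loop-helix transcription factor, went from 1.22 ± 0.17 to 12.1 ± 5.22 CPM (SD, n = 3 and 2), a 9.84-fold change. Nefh, the neurofilament heavy chain, rose 5.93-fold to 91.7 ± 22.9 CPM, and Usp31, a deubiquitinase, rose 4.48-fold to 30.1 ± 3.97 CPM. The histone gene H2ac24 rose 4.12-fold, with 506 and 474 CPM in the knockouts against 96.1, 134 and 127 CPM in the controls. Gbp5, an interferon-induced GTPase, rose 3.69-fold, and the serpin Serpina3f rose 3.62-fold. The other leading rises were Rrp12, a ribosome assembly factor (2.82-fold), Btaf1, an ATPase that acts on the TATA-binding protein (2.74-fold), Scyl2, a pseudokinase of vesicle traffic (2.54-fold), and Hells, a chromatin remodeller of dividing cells (2.45-fold). These 10 genes had edgeR adjusted p from 0.0428 to 0.0498, and both knockouts lay above every control. With libraries scaled to equal T cell gene levels all 10 stayed above 0, from 0.48 for Scyl2 to 2.44 for Msc on the log2 scale, and only Nefh passed (edgeR adjusted p = 0.0361, range over all settings and tools 4.23e-11 to 1). That scaling moved the median of all genes to -0.89, while the smallest of these log2 rises was 1.29, so their sign could hardly turn.

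The largest falls included genes that were nearly undetected in the knockouts. Bahcc1 went from 10.5 ± 5.21 to 0.0369 ± 0.0192 CPM and the tetraspanin Tspan7 from 10.7 ± 6.33 to 0.0837 ± 0.0469 CPM (SD, n = 3 and 2). Tspan15, another tetraspanin, fell from 40.5, 34.6 and 36.9 CPM in the controls to 2.55 and 0.514 CPM in the knockouts, and Morc4 from 8.98 ± 1.52 to 0.434 ± 0.136 CPM. Scd1, the stearoyl-CoA desaturase, was 16.8-fold lower and Cyp39a1, an oxysterol hydroxylase, 14.7-fold lower. Enho (14.1-fold), Cpne4 (14.1-fold), Kctd15 (12.1-fold) and the phospholipase gene Plcb4 (12.1-fold) were lower as well. These 10 genes had edgeR adjusted p from 0.0428 to 0.0486. Melanocyte RNA moved the same way in the same libraries: Dct fell from 4231 ± 1229 to 687 ± 192 CPM, a log2 fold change of -2.62 ± 0.329, and Sox10 by -2.61 ± 0.357 (both edgeR adjusted p = 0.0428).

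Cell cycle genes were higher as groups by camera with the preset correlation only. Of 36 G1/S genes 1 rose over all genes tested, Hells, and 28 rose when adjusted over the list alone. Both knockouts lay above every control for 31. Chance gives 10% for a single gene, but genes of a list can move together, so this count is no test of the list. In the ribosomal list, which did not pass camera, 30 of 76 did the same. The list passed camera (adjusted p = 5.92e-15, median log2 fold change 0.82), but not with an estimated correlation (adjusted p = 0.73 with an estimated correlation). Examples are the ribonucleotide reductase subunits Rrm2, at 506 ± 56.3 CPM in controls and 897 ± 35.2 CPM in knockouts, and Rrm1, at 430 ± 29.1 and 756 ± 97.8 CPM, neither past the edgeR threshold over all genes (adjusted p = 0.05 and 0.0503). Of 38 G2/M genes only Ccna2, a cyclin, rose over all genes tested (1.90-fold, edgeR adjusted p = 0.0428), while 7 rose and 1 fell adjusted over the list alone. That list had a camera adjusted p of 5.02e-05 and a median of 0.41 (adjusted p = 0.73 with an estimated correlation). The melanocyte share was lower and the T cell share higher in the same knockouts, and scaled to equal T cell gene levels the medians were -0.03 for G1/S and -0.47 for G2/M, against -0.89 for all genes.

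Some T cell lists, and the class I presentation and proteasome lists, passed camera upwards with the preset correlation. None of the 29 T cell receptor and co-stimulation genes passed over all genes tested and 1 rose adjusted over the list alone. Both knockouts exceeded every control for 19 of them. Chance gives 10% for a single gene, but these genes can move together, so the count is no test of the list. Camera gave an adjusted p of 1.31e-08 with a median of 0.74 (adjusted p = 0.73 with an estimated correlation). The adaptor Lat was at 112 ± 24 CPM in controls and 241 ± 0.96 CPM in knockouts (edgeR adjusted p = 0.0542). Cytotoxic effector genes (camera adjusted p = 0.0107, median 0.45), cytokine receptors (0.0321, 0.62), effector differentiation genes (0.0321, 0.39), class I antigen presentation (0.000297, 0.40) and proteasome subunits (0.0327, 0.16) passed as well. Each of these lists also had an adjusted p of 0.73 with an estimated correlation. Scaled to equal T cell gene levels, their medians were -0.26 for cytotoxic genes, -0.17 for cytokine receptors, -0.39 for effector differentiation, -0.46 for class I presentation and -0.72 for proteasome subunits, against -0.89 for all genes. The calls of the cytotoxic, cytokine receptor, effector differentiation and proteasome lists were lost without Control 3 (camera adjusted p = 0.0879, 0.0885, 0.193 and 0.0711) and without KO 3 (0.0521, 0.0521, 0.0882 and 0.0521), and that of the proteasome also without Control 2 (0.216), with library totals only (0.136) and with a filter of 5 CPM in 2 libraries (0.114). Without Control 2 the cytotoxic median was 0.81 and the effector differentiation median 0.73, and without KO 3 the cytotoxic median was 0.29. Gzmb, the main granzyme of cytotoxic T cells, was the most abundant gene of both knockouts and stood at 2603 ± 1900 CPM in controls and 11750 ± 1538 CPM in knockouts, a log2 fold change of 2.17 ± 0.532 (edgeR adjusted p = 0.0885). Gzmc was at 151 ± 72.4 and 604 ± 25.8 CPM (edgeR adjusted p = 0.0533) and Il2ra, the high-affinity IL-2 receptor chain, at 87.7 ± 35.9 and 329 ± 45.9 CPM (edgeR adjusted p = 0.0507). In the cytotoxic list 0 genes rose and 1, Lamp1, fell over all genes tested, while 2 rose and 1 fell adjusted over the list alone; in the cytokine receptor list 0 passed over all genes and 3 rose and 4 fell adjusted over the list alone. Class I presentation had 0 and 10 rises by these counts, among them Psmb8 at 666 ± 125 and 1149 ± 45.4 CPM and Tap2 at 311 ± 53.3 and 500 ± 25.1 CPM, and effector differentiation and proteasome genes had 0 in both.

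Melanocyte and macrophage markers, mitochondrial transcripts and oxidative phosphorylation genes were lower as lists with the preset correlation. Of 16 melanocyte markers 7 fell over all genes tested and 16 adjusted over the list alone (camera adjusted p = 1.07e-20, median -2.33; adjusted p = 0.73 with an estimated correlation). Of 23 macrophage and monocyte markers 0 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 6.04e-07, median -1.78; adjusted p = 0.73 with an estimated correlation), with Lyz2 at 933 ± 565 CPM in controls and 188 ± 4.05 CPM in knockouts. The macrophage median was -0.95 without Control 1 and -0.74 with Control 2 as the only control. The 13 mitochondrially encoded mRNAs had a median of -0.60 (camera adjusted p = 0.00137; adjusted p = 0.73 with an estimated correlation), 0 falls over all genes and 4 adjusted over the list alone. Their call was lost with the melanocyte covariate (camera adjusted p = 0.421). The 45 nuclear oxidative phosphorylation genes had a median of -0.28 and 0 falls by either count (camera adjusted p = 0.00415; adjusted p = 0.771 with an estimated correlation). With Control 2 as the only control their median was -0.07.

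**Figure D3:**
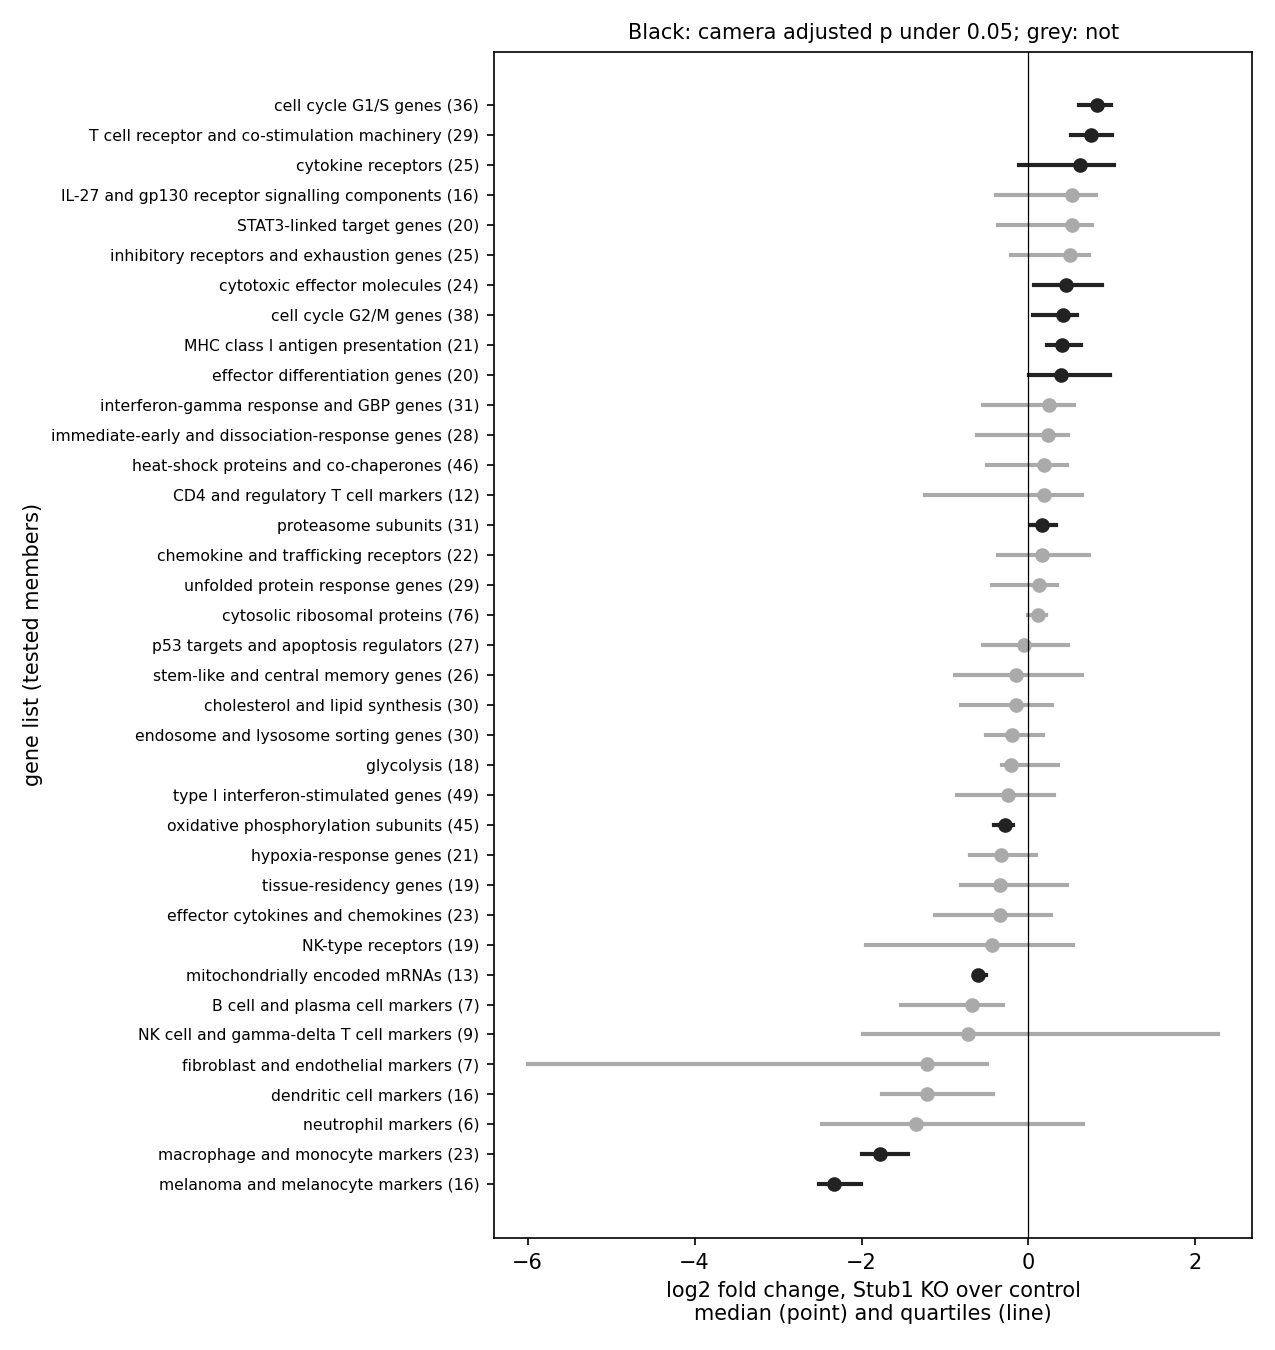
Median log2 fold change (point) and quartiles (line) of the tested members of each gene list with at least 5 tested members, Stub1 KO over control; black lists passed camera at an adjusted p under 0.05 with a preset correlation. G1/S genes lead with a median of 0.82 and melanocyte markers are lowest with -2.33. Scaled to equal T cell gene levels the G1/S median is -0.03, against -0.89 for all genes.

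The remaining 26 of the 38 lists did not pass camera. The 16 IL-27 and gp130 receptor signalling genes had a median of 0.52 (camera adjusted p = 0.0592, or 0.73 with an estimated correlation) and 0 calls. With the preset correlation this list passed without Control 1 (0.047) and without Control 2 (0.00522). Among its genes Stat3 was at 566 ± 179 CPM in controls and 986 ± 30.2 CPM in knockouts (edgeR adjusted p = 0.144). STAT3-linked targets had a camera adjusted p of 0.11 with 0 calls over all genes. Exhaustion genes had a camera adjusted p of 0.0592 and 0 calls, type I interferon-stimulated genes 0.986 and 0 calls, and stem-like genes 0.965 with 1 fall, Klf3, at 37.9 ± 7.19 CPM in controls and 11.5 ± 0.96 CPM in knockouts. The exhaustion list passed without Control 2 and without KO 1 (camera adjusted p = 0.00011 and 0.0387; with an estimated correlation on all libraries 0.771). Other lists here that passed with the preset correlation when some library was left out were interferon-gamma, effector cytokine, trafficking receptor, heat-shock, lipid, hypoxia, ribosomal, dendritic, CD4 T cell and fibroblast genes. Only in the IL-27, heat-shock, lysosomal, glycolysis and dendritic lists did the median stay within 1.5 times its value whichever library was left out. Most medians of lists that did not pass are therefore not given. Interferon-gamma response genes had 2 rises, Gbp5 and Serpina3g (camera adjusted p = 0.0592). Heat-shock proteins and co-chaperones, the partners of the ligase, had 0 calls over all genes and 6 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0592, median 0.19). Lipid synthesis genes had 2 falls, Scd1 and Fads2 (camera adjusted p = 0.0592), and the tissue-residency list had 1 fall, Dusp6 (camera adjusted p = 0.503). The lysosomal list had 1 fall, Lamp1, at 538 ± 68.4 CPM in controls and 216 ± 42.5 CPM in knockouts (camera adjusted p = 0.131, median -0.20), the p53 list 1, Phlda3 (0.845), the unfolded protein list 1, Trib3 (0.965), and the fibroblast and endothelial list 1, Sparc (0.0592). Effector cytokines (0.503), NK-type receptors (0.845), trafficking receptors (0.432), immediate-early genes (0.604), glycolysis (0.986), hypoxia (0.123), ribosomal proteins (0.055), and markers of dendritic cells (0.146), neutrophils (0.757), B cells (0.653), CD4 T cells (0.12) and NK or gamma-delta T cells (0.856) had 0 calls, with camera adjusted p in parentheses. The list of the 3 named genes of the study held the fall of Stub1 (camera adjusted p = 0.507). Adjusted over the list alone, 4 STAT3-linked targets rose and 2 fell, 5 interferon-gamma genes rose, 1 lipid gene rose and 8 fell, and 2 unfolded protein genes rose and 4 fell. By the same count 4 lysosomal, 4 dendritic, 3 tissue-residency, 2 hypoxia and 2 fibroblast or endothelial genes fell, 1 fell in the p53 list and 1 in the stem-like list. Further, 2 glycolysis genes rose and 1 fell, 3 CD4 T cell markers rose and 1 fell, 1 neutrophil marker rose and 2 fell, and the NK or gamma-delta list and the list of named genes had 1 rise and 1 fall each, while the other lists here had 0. In 10 lists, none of them past camera, the median or the mean had another sign than the camera direction.

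**Figure D4:**
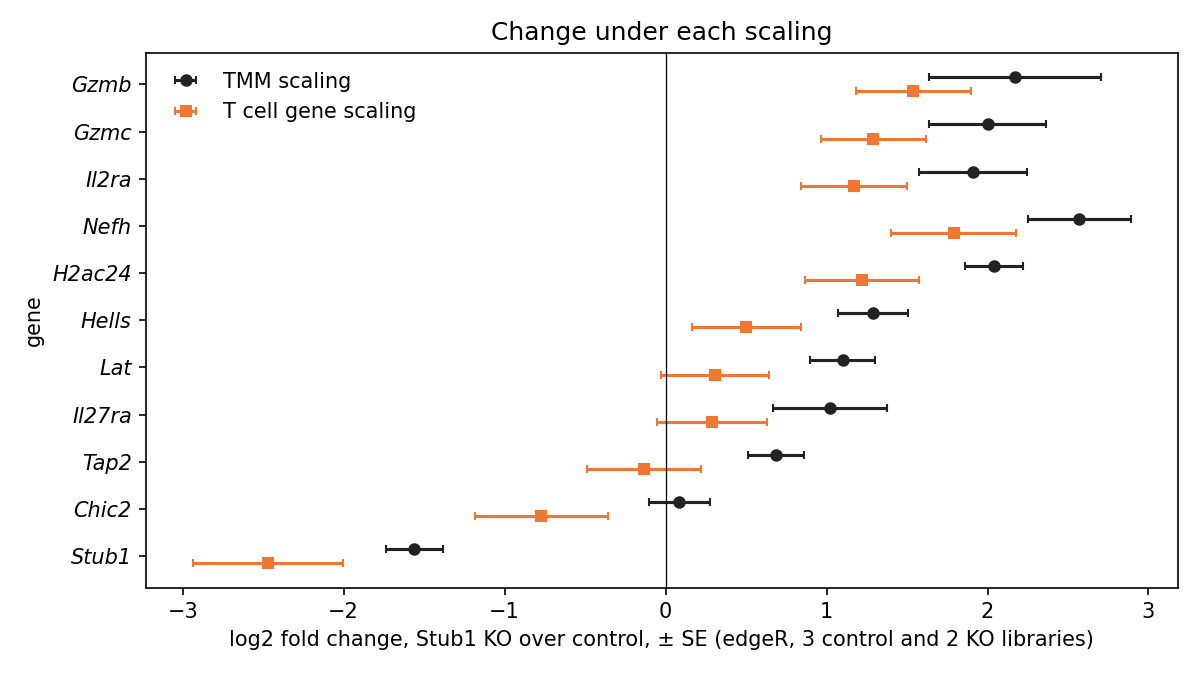
Log2 fold change (Stub1 KO over control, ± SE, 3 control and 2 KO libraries) of 11 genes with TMM scaling (black circles) and with libraries scaled to equal T cell receptor and co-stimulation gene levels (orange squares). Gzmb goes from 2.17 to 1.54, Il27ra from 1.02 to 0.29 and Stub1 from -1.56 to -2.47. The T cell gene scaling moves the median of all genes to -0.89.

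The authors' deposited table has 2516 genes at an adjusted p under 0.05, 862 higher and 1654 lower. It holds 259 of the 269 edgeR calls, and 258 of these passed there in the same direction. Across the 11979 genes in both, Spearman's rho of the fold changes was 1, computed from the same counts. Between libraries, the log2 levels of Control 2 were about as close to KO 1 (Spearman's rho 0.965) as to Control 3 (0.961), and less close to Control 1 (0.941). The edgeR count rested on particular libraries: without Control 1, Control 3, KO 1 or KO 3 edgeR gave 0 calls (1695 to 3053 genes at an unadjusted p under 0.05, and 2598 at an adjusted p under 0.05 by DESeq2 on all 5 libraries), and without Control 2 it gave 2335. With a melanocyte covariate, or with Control 2 as the only control, edgeR also gave 0 calls, with 193 and 2629 genes at an unadjusted p under 0.05.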

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

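The melanocyte covariate, the T cell gene scaling, the submitters' filter and the fit with only Control 2 were chosen after seeing the data. The fall of Stub1 kept its direction in every setting run. It lost its call with the melanocyte covariate (-1.39), with only Control 2 (-1.36), and against a fold threshold of 1.5 (-1.56). The call was also lost without Control 1, Control 3, KO 1 or KO 3, and was kept without Control 2. With each library left out the Stub1 change ran from -1.65 to -1.47. The 269 calls became 423 with library totals only, 761 with a filter of 5 CPM in 2 libraries, 845 with the submitters' filter, 1273 at a threshold of 0.1, 2598 with DESeq2 and 2620 with limma-voom quality weights. The T cell gene scaling gave 862 calls, 8 higher and 854 lower, and moved the median of all genes to -0.89. Calls numbered 0 with the melanocyte covariate, 0 with only Control 2 and 0 against the fold threshold in edgeR (193, 2629 and 1907 genes at an unadjusted p under 0.05), and 0 to 2335 with each library left out; fits with 1 knockout assume that it varies like the controls. Beyond fewer samples and the covariate's overlap with the groups, the cause was not tested. The 20 genes named for the largest changes kept direction where tested, which selection largely fixed.

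The 12 lists past camera became 0 with an estimated correlation, 0 with fry (lowest adjusted p 0.101), and 9 to 18 with each library left out. The melanocyte covariate, which leaves little of the group difference to test, kept only the G2/M and proteasome calls; those of G1/S and mitochondrial genes were lost. The direction given by camera turned there, though the stem-like and melanocyte medians kept their sign, for cytokine receptors (median -0.77), class I presentation (-0.15), exhaustion (-1.0), stem-like (-1.38), cytotoxic (-1.09), effector differentiation (-0.93), trafficking receptors (-1.5), T cell receptor (-0.84), immediate-early (-0.72), oxidative phosphorylation (0.052), hypoxia (0.42), melanocyte (-0.20) and macrophage (0.33) lists. Lists with no call in either fit that also turned were IL-27 and gp130 signalling (-0.44), STAT3-linked (-0.68), lysosomal, lipid, p53, B cell and CD4 T cell genes. T cell gene scaling kept 8 of the 12 calls and lost those of the proteasome (median -0.72 against -0.89 for all genes), class I presentation, G2/M and cytokine receptor lists (limma camera adjusted p = 0.614, 0.388, 0.388 and 0.059). The proteasome call was also lost with library totals only, the filter of 5 CPM and the replicate block (0.277), and that of effector differentiation with the filter (0.0513). With only Control 2 the control group is 1 library and the spread comes from the knockouts alone, so list calls of that fit are not given. Its medians were 0.12 for cytokine receptors, 0.05 for cytotoxic and -0.06 for effector differentiation genes. They were -0.07 for oxidative phosphorylation and 0.24 for type I interferon genes. Sign changes of genes with no call in either fit were not counted as turns: the covariate had 52 among the 153 named genes besides Stub1, Il27ra with -0.84 and Gzmb with -0.80 among them.

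No pairing by replicate number was seen: the difference between the shared numbers 1 and 3 correlated at -0.0243 across genes between the groups. That is a single contrast per group, so it cannot show that the libraries are unpaired. With the replicate block the counts were 1588 genes (815 higher, 773 lower) and 20 lists; Control 2 has no partner there, so it carries no weight. The alternative that includes Stub1 KO 2 was not run. In the simulation 7% of 2-fold changes were recovered.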

Other observations

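All tests of explanations given here were chosen after the results were seen. The T cells of every library used nearly the same receptor segments. Trbv12-1 made up 99.49, 99.63 and 99.77% of Trbv counts in Control 1, Control 2 and Control 3 and 99.8 and 98.75% in KO 1 and KO 3 (exact 95% interval of the lowest value 98.62 to 98.88%). Trav14d-1 made up 82.71 to 89.64% of Trav counts in the controls, 70.27% in KO 1 (exact 95% interval 68.93 to 71.59%) and 81.3% in KO 3. Segments of these families form the V beta 5 and V alpha 2 chains that the ovalbumin-specific OT-I receptor uses; the labels name no receptor. Of 37 receptor and immunoglobulin genes tested 0 passed in edgeR. Trbc2 was at 1129 ± 319 CPM in controls and 1196 ± 242 CPM in knockouts (SD, n = 3 and 2), with a log2 fold change of 0.08, while the median of the T cell receptor and co-stimulation list was 0.74.

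Trib3, a gene of the integrated stress response, fell from 93.7 ± 19.9 to 26.5 ± 0.728 CPM (edgeR adjusted p = 0.0428). Chac1 and Ddit3 belong to the same response and did not pass (edgeR adjusted p = 0.0557 and 0.0645). Chac1 was at 28 ± 7.25 CPM in controls and 5.96 ± 2.35 CPM in knockouts. Ddit3 was at 69.1, 39.5 and 58.5 CPM in controls and 21.6 and 16.2 CPM in knockouts. For Trib3, Chac1 and Ddit3 the log2 fold changes were -1.82, -2.24 and -1.56. With the melanocyte covariate, which overlaps with the groups, they were -1.16, -0.32 and 0.13. Of the 29 tested genes in the unfolded protein list, which holds these genes, both knockouts lay above every control for 9 and below for 6. Of the 20 tested genes nearest to Stub1 in chromosomal order, 10 on either side, 0 passed in edgeR, with 3 at an unadjusted p under 0.05 and a median log2 fold change of -0.35; the adjacent Jmjd8 had -0.38 ± 0.317.

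The 237 genes lower in the knockouts may reflect a larger share of melanoma and macrophage RNA in the controls. Of these genes 84.8% had their lowest control level in Control 2, the control with the least marker RNA. The share was 34.0% for the 10173 uncalled genes with a mean of at least 5 CPM, and this is a statement about 1 library. The 32 higher genes mirrored it, with 68.8% highest in Control 2 against 39.1% of the uncalled genes. Control 2 thus lay nearest to the knockouts. Genes called lower would tend to be lowest there under any cause, so the share cannot single out tumour RNA. Of the 237 lower genes, 7 are melanocyte markers themselves. No sort or gate that would remove tumour cells or macrophages is given in the sources used here, and 0 of the 16 melanocyte and 2 of the 23 macrophage markers are also in another list. A difference in library size is argued against by the totals: the controls, at 49122747 to 63003087, lie between KO 1 (41318384) and KO 3 (90689080). Over these genes KO 3 and KO 1 differed by a median of -0.17 against a median change of -2.40. The test favours genes with a small spread within groups, so that small difference cannot decide on library size. In 14 of the 237, Bahcc1, Tspan15, Scd1 and Cyp39a1 among them, the fall went beyond that of every melanocyte marker (-2.72) by more than 2 standard errors. These are the extremes of the calls, and the error of the marker itself was not counted. Several had low means, such as 2.24 CPM for Gpr153 and 4.01 CPM for Cdsn. What sets these genes apart stays open. An effect of Stub1 loss in the T cells, or on how many tumour cells came along, was not tested apart from the groups.

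The higher T cell genes, Il27ra among them, may reflect T cell RNA that was less diluted by tumour RNA. The median log2 fold change of the T cell list was 0.744. Trbc2 changed by 0.083 ± 0.254, Trbv12-1 by -0.06 ± 0.281 and Trav14d-1 by 0.295 ± 0.399 (edgeR, ± SE). Dilution alone would raise these receptor transcripts as well, so they and the list give different answers. Scaled to equal T cell gene levels, the change of Il27ra went from 1.02 ± 0.354 to 0.29 ± 0.343, less than its standard error. The same scaling left Gzmb at 1.54 ± 0.355 and Gzmc at 1.29 ± 0.326 (edgeR adjusted p = 0.0388 and 0.0491, over all settings and tools 9.92e-05 to 1 and 9.1e-07 to 1). It moved the median of all genes to -0.89, so unscaled log2 rises of 2.17 and 2 could hardly reach 0. The scaled values show only that both granzymes rose by more than the T cell list, and they cannot decide on dilution. The melanocyte covariate, which overlaps with the groups, gave -0.80 for Gzmb and 0.12 for Gzmc, both with an edgeR adjusted p of 1, so the size of their change stays open. Among the controls alone, Gzmb was higher in Control 2 by more than the T cell list, whose median was higher there by 0.875. The scaling can therefore leave a Gzmb difference that does not come from Stub1. It also assumes that the T cell list itself did not change with Stub1, which these libraries cannot show. Trbc2 and Trbv12-1 did not rise as that list did.

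For the higher cell cycle genes, dilution and a change in dividing T cells cannot be told apart. After T cell gene scaling the G1/S median was -0.025, and that of all genes was -0.89. Dilution would give such a G1/S value if tumour cells added no G1/S RNA, which was not tested. But against Control 2 alone the knockouts were higher by a median of 0.56 for G1/S genes and 0.24 for the T cell list, and that rests on 1 library. The melanocyte covariate left the G1/S median at 0.085 (camera adjusted p = 0.0812) and the G2/M median at 0.45 (9.08e-05), while T cell gene scaling put the G2/M median at -0.47 (0.388), so these corrections split the lists in opposite ways. A difference in library size is argued against, since KO 3 and KO 1 differed by a median of 0.0231 over the G1/S list. An effect of Stub1 on proliferation stays open as untested.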
